A study of Mus musculus with 5 samples.

How the data were processed

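Reduced representation bisulfite sequencing was used on 5 mouse libraries, which the titles place in 3 groups: 1 WT library, 2 libraries named K36M and 2 named K9M. Per the labels' protocols, genomic DNA was cut with MspI, which enriches CpG-rich fragments, and treated with bisulfite, which converts unmethylated cytosines so that methylated ones can be told apart. K36M and K9M stand for histone H3 lysine-to-methionine mutants, and the series title places them in the H3.3 variant. The source name calls the cells HSCs (hematopoietic stem cells), while the growth protocol describes sorting from peripheral blood, and this disagreement was left open. The K36M and K9M mice received 2 mg/ml doxycycline in the drinking water, per the labels' protocols. Nothing in the labels says that the replicates are separate animals, so p-values measure only the spread between these samples, which may be technical.

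The submitters' processing notes name cutadapt, BSMAP and the mm9 build, with no versions or settings. Each deposited table lists CpG positions with a methylation level as a fraction and a total count. How the fraction was computed, and whether reads were deduplicated, is not given in the sources used here. All positions below are mm9, counted from 1. The gene table at hand belongs to another build, GRCm38.p6, so no gene, promoter or gene body was assigned to a position, and the lists of imprinted, germline, lineage and chromatin genes fixed before the data were examined were not tested.

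The deposited fraction was taken to be on another scale in K9M replicate 2 than in the other 4 libraries, a reading inferred from the values below. At CpGs with a total count of at least 20 in every library that were at 98% or more in K9M replicate 2, the median deposited level was 54.4% in WT, 53.2% and 55.0% in the K36M libraries and 56.8% in K9M replicate 1. The deposited total also rose with the level in those 4 libraries. Relative to K9M replicate 2, it was 2.28, 2.20, 2.25 and 2.37 times as large at such CpGs as at unmethylated ones, in the order WT, K36M replicate 1, K36M replicate 2 and K9M replicate 1. A total that holds methylated reads plus a second count of reads of either kind, counted at the rate seen at fully methylated CpGs, would give 2.19, 2.14, 2.22 and 2.32, and a plain read total would give 1. Among CpGs with a total of 2, the level was exactly 0.5 in 82.9% to 85.8% of cases in the 4 libraries and in 18.4% in K9M replicate 2. The 4 libraries were therefore read as a methylated count and a second count, the total minus the methylated count, that follows reads of either kind. It is smaller than the number of reads, at 0.76 to 0.879 per methylated read at fully methylated CpGs, so the ratio of the 2 counts can pass 1. In K9M replicate 2 the deposited total was taken as the second count. The step of the authors' processing that would make the difference is not known.

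The methylated count is the product of level and total, rounded. The product was whole within 0.01 for 100% of CpGs with totals under 1000 in the 4 libraries and for 89.2% in K9M replicate 2, whose levels are mostly rounded to 3 decimals. The ratio of the methylated count to the second count was divided by the library's plateau, the median ratio over the 20% of tiles with the highest mean rank, which was 1.23 in WT, 1.22 and 1.26 in K36M and 1.37 and 0.954 in K9M. The result is called the relative level, in percent of the plateau. A change that scales all CpGs of a library alike cannot be seen on it, and it can pass 100%. This scaling was chosen after the values had been seen.

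CpGs needed a second count of at least 10 in all 5 libraries, which left 1780536 autosomal CpGs. Tiles of 1 kb with at least 3 such CpGs numbered 152678 and held 1642128 CpGs. The design fixed before the data were examined was a logistic model per tile with quasi-binomial dispersion across replicates, moderated with limma's squeezeVar (limma 3.58.1 in R 4.3.3) on a trend in log mean count, held at or above 1, an F test of the deviance and Benjamini-Hochberg adjustment. It was applied to the methylated and second counts, in place of methylated and unmethylated reads, with the log plateau as a library offset. A tile was called at an adjusted p under 0.05 with a difference of at least 10 points between group means. All 5 libraries entered one fit with 2 residual degrees of freedom, both from the mutant pairs, so the lone WT library is assumed to vary like the mutants. limma on relative levels was fitted first and its counts of calls were seen before the logistic model of the fixed design was returned to; both sets of counts are printed. The counts of a tile's CpGs are summed although CpGs on the same read are not independent. Only the moderated replicate dispersion can account for it. That dispersion lay above the floor of 1 in 22.35% of tiles, and the others were tested at the floor.

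The fit was tested on simulated data for 152678 tiles. Earlier simulations, with beta-binomial counts and then with reads shared among CpGs, did not match the observed dispersion and recovered none of the changed tiles. The version used draws counts from each tile's own totals and fitted dispersion, so it tests the computation and does not establish the error rate in the real data. With 200 tiles lowered in K36M, the comparison of K36M with WT recovered 0% of those lowered by 10 points, 2% by 20, 26% by 30 and 44% by 40; with 800 lowered tiles the shares were 0%, 2.5%, 21% and 50.5%. For K36M against K9M, 200 lowered tiles gave 0%, 4%, 38% and 70%. With no change simulated, 0 tiles were called in K36M against WT, 1 in K9M against WT and 0 in K36M against K9M. The lowered tiles were all drawn from those at a level of 50% to 80%, and tiles at other levels were not simulated with a change. With the totals and dispersions of such tiles, simulated differences of 20 points or less were thus mostly missed.

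The deposited totals came to 174743796 counts in WT, 133165295 and 165100774 in K36M and 140793468 and 111738339 in K9M, not comparable under this reading. The median second count per common CpG was 43 in WT, 35 and 42 in K36M and 34 and 44 in K9M. Intervals of 95% for the WT level of a named tile were drawn from the 2-count reading with the mean reads per CpG as the number of reads. Intervals and limits cover counting error only, since PCR copies are not independent molecules.

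Tiles were classed by the number of CpG positions listed in any library (3 to 9, 10 to 19, 20 to 39, 40 or more) and by mean relative level over the 5 libraries (under 20%, 20% to 80%, over 80%). Named tiles are, by a rule fixed before the data were examined, the 5 called tiles with the largest difference in each direction of each comparison where every library of a group lies beyond every library of the other, passing over tiles within 2 kb of a named one. X, Y and the mitochondrial genome stayed out of the main tests. Alternatives were other coverage minimums, tile sizes and CpG numbers, single CpGs, other difference thresholds, edgeR 4.0.16's quasi-likelihood test, limma on log2 ratios with a pseudocount of 1, no dispersion floor, the X chromosome, removal of very deep CpGs, a replicate block and each library left out. Added after seeing the data were other plateaus, deposited levels without rescaling, limma on relative levels, level classes set by the K9M libraries and class means without each mutant library. Tables were made with Python 3.11.15, pandas 2.3.3 and scipy 1.17.1.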

Results

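DNA methylation was measured at single CpGs in 5 mouse libraries: 1 WT, 2 K36M and 2 K9M. The mutants replace lysine 36 or lysine 9 of histone H3 with methionine, and the question the series title names is the level of methylation in H3.3 mutant hematopoietic stem cells. Between 3356656 and 3534966 CpGs were listed per library. Levels are given in percent of each library's plateau, because CpGs near 100% in K9M replicate 2 were deposited at medians of 53.2% to 56.8% in the other 4 libraries. A different unit was inferred from the deposited totals, the results below rest on that reading, and levels as deposited gave 0 called tiles in all 3 comparisons. WT has no replicate.

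**Figure D1:**
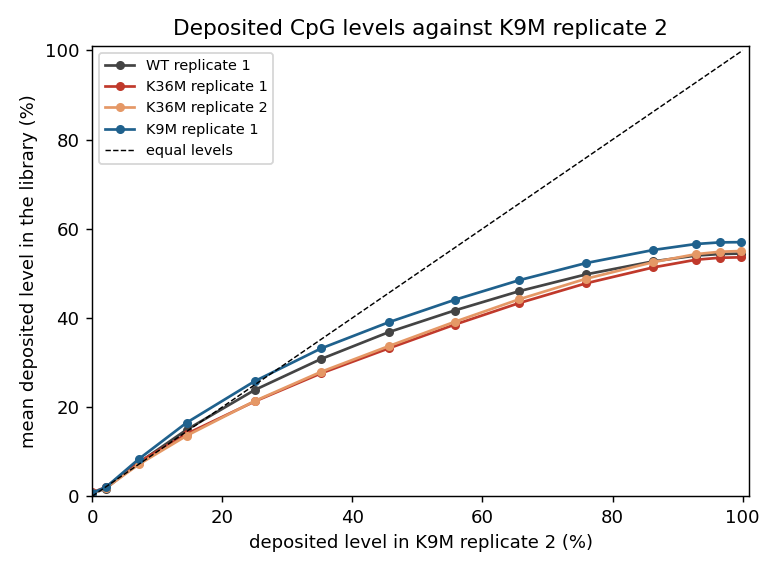
Mean deposited level of CpGs in 4 libraries (y axis, percent) against the deposited level of the same CpGs in K9M replicate 2 (x axis, percent), binned by the latter; the dashed line marks equal levels. CpGs near 100% in K9M replicate 2 lie between 53.2% and 56.8% (medians) in the others.

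Over 1780536 autosomal CpGs, the pooled relative level was 42.6% in WT, 41.5% ± 0.151 (SD, n = 2) in K36M and 42.2% ± 0.102 (SD, n = 2) in K9M. K36M lay 0.742 points below K9M, with an exact two-sided permutation p of 0.333, the smallest that 2 libraries against 2 allow. The lone WT library was not tested against either mutant on this value. K36M lay below WT by more than the replicate SD, at -1.12 points, and stayed below it under the alternatives tried, at -0.614 points with the plateau from the top 40% of tiles and -0.551 points with deposited levels. The order of K36M and K9M turned with the plateau: with the plateau from the top 40% of tiles, K36M lay 0.096 points above K9M. With the mean of CpG levels in place of pooled counts, K9M lay 0.519 points above WT instead of below it. Neither K36M against K9M nor K9M against WT thus had a direction that held under all settings.

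Tiles of intermediate methylation were lower in both K36M libraries. In the 20145 tiles with a mean level of 20% to 80%, the mean level was 60.4% in WT, 53.9% ± 0.0942 (SD, n = 2) in K36M and 61.9% ± 2.64 (SD, n = 2) in K9M. K36M replicates 1 and 2 were at 53.8% and 53.9%, and K9M replicates 1 and 2 at 60.1% and 63.8%. The mean difference from WT was -6.58 points in K36M, and -5.53 points with classes set by the K9M libraries. The 5-library mean includes K36M, so a large loss can itself place a tile at 20% to 80%. The difference lay below 0 on all 19 autosomes in both K36M libraries, from -5.10 to -7.72 points. In K9M the mean difference was -0.385 points in replicate 1 and 3.35 points in replicate 2, so K9M was not separated from WT by the spread of its replicates. K9M replicate 2 lay above WT on all 19 autosomes, by 2.56 to 3.89 points, and replicate 1 below it on 15 of 19. One sign on all autosomes is thus no separate evidence, since a single K9M library also had it. Both K36M libraries lay below WT in 57.2% of these tiles and both above it in 16.7%, where 33.3% each would come from libraries in random order; for K9M the shares were 28.9% and 39.7%. Tiles are not independent replicates, and these shares have no test.

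In the 101550 tiles over 80%, levels were 93.8% in WT, 92.2% ± 0.840 (SD, n = 2) in K36M and 95.0% ± 2.24 (SD, n = 2) in K9M. The K36M difference from WT there, -1.65 points, was -0.598 points with the plateau from the top 40% of tiles and -1.06 points without K36M replicate 1. K9M replicate 2, the library with higher levels as deposited, was 2.74 points above WT there and K9M replicate 1 was -0.424 points from it. In the 30983 tiles under 20%, levels were 3.24% in WT, 2.96% ± 0.182 (SD, n = 2) in K36M and 3.38% ± 0.0536 (SD, n = 2) in K9M.

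**Figure D2:**
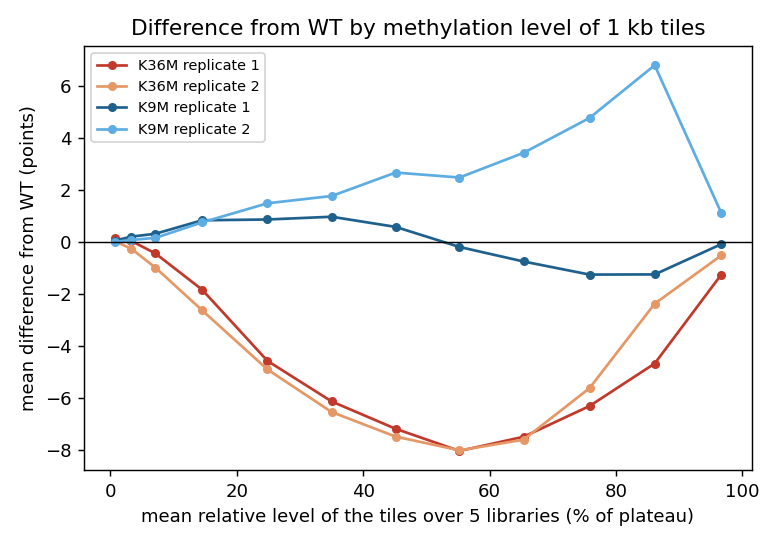
Mean difference from WT (y axis, points of relative level) of 1 kb tiles in bins of their mean level over the 5 libraries (x axis, percent of plateau), a line per mutant library. Both K36M lines reach about -8 points, -8.05 and -8.03, in the bin from 50%. K9M replicate 2 rises to 6.80 points in the bin from 80%, where K9M replicate 1 is at -1.25. The mean includes K36M, so a tile with a large loss in K36M can itself fall in a middle bin and deepen the K36M lines there.

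The mean difference of K36M from WT was largest in CpG-poor tiles. Those tiles also had the highest levels, and CpG number was not separated from level. Other plateaus were not run on these classes. In tiles with 3 to 9 CpGs, the level was 83.2% in WT, 80.3% ± 0.585 (SD, n = 2) in K36M and 84.4% ± 2.26 (SD, n = 2) in K9M. With 10 to 19 CpGs, the values were 75.1%, 73.3% ± 0.682 and 76.3% ± 2.03 (SD, n = 2 per mutant). With 20 to 39 CpGs they were 49.5%, 49.0% ± 0.413 and 49.9% ± 0.718. In tiles with 40 or more CpGs, the class nearest to CpG islands, they were 14.0%, 14.0% ± 0.0776 and 13.9% ± 0.0993, and the K36M difference from WT, -0.0316 points, was within the spread of the replicates.

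The comparison of K36M with WT asks where methylation differs in the lysine 36 mutant. Of 152678 tiles, 924 were lower and 35 higher in K36M, so 96.4% of calls were losses. The called losses had a median difference of -27.4 points, and 168 of them were 40 points or more. At these 924 tiles the mean level was 47.0% in WT, 18.7% and 18.5% in the K36M libraries and 46.4% and 47.3% in the K9M libraries. The tiles were chosen for the K36M and WT levels, and the K9M replicates entered the dispersion. Losses fell in tiles of 20% to 80% in 679 cases, under 20% in 237 and over 80% in 8. The class is set by the mean over the 5 libraries, K36M included. A large loss from a high level can thus itself place a tile at 20% to 80%, and these counts do not give the level without the loss. By CpG number, 434 lay in tiles with 3 to 9 CpGs, 335 with 10 to 19, 118 with 20 to 39 and 37 with 40 or more, which is 5.42, 8.12, 6.44 and 2.85 per 1000 tiles of each class, with no steady fall as CpGs became denser. Tiles with 20 or more CpGs were called lower in 0.495% of cases and sparser tiles in 0.634% (Fisher's exact test, two-sided, odds ratio 0.780, p = 0.00422, adjusted p = 0.00633 over 6 tests), a test that treats tiles as independent. CpG number was not separated there from level or from the counts summed per tile. Calls per 1000 tiles ran from 3.17 on chromosome 1 to 10.6 on chromosome 11.

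The number of calls depended on the test, while losses outnumbered gains under each test that made calls. limma on relative levels called 3 lower and 0 higher tiles, edgeR's quasi-likelihood test 1554 and 66, and single CpGs gave 0 calls in either direction with 4285 CpGs at an unadjusted p under 0.05. Without K9M replicate 2 the logistic model called 2033 lower tiles, without K9M replicate 1 it called 2028, without K36M replicate 1 it called 1834 and without K36M replicate 2 it called 1549, in fits with 1 residual degree of freedom. Higher tiles in these fits numbered 123 to 159 in place of 35, and the share of losses was 91.6% to 94.3%.

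**Figure D3:**
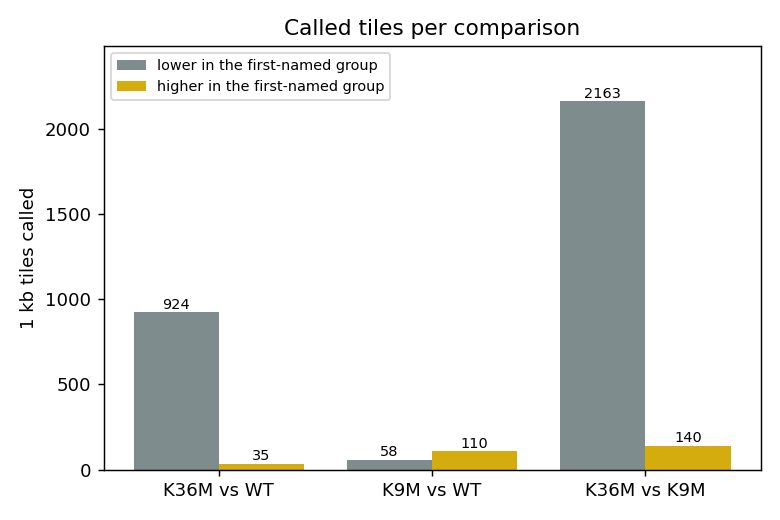
Number of 1 kb tiles called (y axis, from 0) lower or higher in the first-named group of each of the 3 comparisons (x axis), by the logistic model at an adjusted p under 0.05 and a difference of at least 10 points. Losses in K36M number 924 against WT and 2163 against K9M.

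The largest loss in K36M against WT lay on chromosome 1 from 78691001 to 78692000 (mm9), with 4 CpGs measured. Its level was 100.0% in WT (95% counting interval 85.4% to 122%), 15.7% ± 1.56 (SD, n = 2) in K36M and 86.7% ± 8.66 (SD, n = 2) in K9M, at an adjusted p of 0.000296 by the logistic model moderated with limma. The tile on chromosome 9 from 114649001 to 114650000 went from 103% in WT to 18.9% ± 5.19 (SD, n = 2) in K36M, with K9M at 94.9% on average. On chromosome 1 from 74065001 to 74066000, WT was at 86.5%, K36M replicate 1 at 5.71% and K36M replicate 2 at 0 methylated counts, which allows a relative level of up to 14.3% in a CpG of average depth. K9M stood at 58.1% ± 0.843 (SD, n = 2) there. Losses on chromosome 17 from 87578001 to 87579000 and from 84364001 to 84365000 took the level from 96.1% to 17.2% ± 5.60 and from 91.8% to 17.2% ± 2.19, with K9M at 84.6% ± 8.86 and 83.3% ± 3.19 (SD, n = 2 each). The second count per CpG in WT lay between 14.7 and 57.7 in these 5 tiles.

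Among gains in K36M, the tile on chromosome 7 from 31930001 to 31931000 had the largest difference, 42.2% in WT against 92.4% ± 0.715 (SD, n = 2), and the K9M replicates stood at 99.6% and 100.2%, so that WT alone was low. On chromosome 1 from 77408001 to 77409000, K36M was at 74.0% ± 6.11, K9M at 62.3% ± 10.7 (SD, n = 2 each) and WT at 30.98%. On chromosome 18 from 36291001 to 36292000 the gain was in K36M without K9M: 65.6% ± 1.95 against 28.2% ± 0.636 (SD, n = 2 each), with WT at 24.98%. The tile on chromosome 19 from 37870001 to 37871000 was alike, at 54.5% ± 8.85 in K36M, 23.8% ± 1.35 in K9M (SD, n = 2 each) and 14.1% in WT. The fifth, on chromosome 2 from 27994001 to 27995000, rose from 24.5% to 63.3% ± 5.41 (SD, n = 2), with K9M at 57.7% ± 10.3 (SD, n = 2), so that WT alone was low. Its call was lost at a coverage minimum of 5 reads, at an adjusted p of 0.0575 by the logistic model moderated with limma. With limma on relative levels, all 10 tiles named for K36M against WT lost their call, at adjusted p from 0.0809 to 0.439 by limma.

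The comparison of K9M with WT gave few calls: 58 tiles lower and 110 higher, with median differences of -23.4 and 26.6 points. limma on relative levels called 3 and 1, and edgeR's quasi-likelihood test 135 and 231. Left-out libraries moved the lower calls to 220 without K9M replicate 1, 258 without K9M replicate 2, 342 without K36M replicate 1 and 341 without K36M replicate 2, and the higher calls to 343, 351, 478 and 478 in the same order. Calls were more frequent in tiles with 20 or more CpGs: 0.0766% against 0.0280% for losses (Fisher's exact test, two-sided, odds ratio 2.74, adjusted p = 0.000539) and 0.131% against 0.0569% for gains (odds ratio 2.30, adjusted p = 0.000141). These were 24 and 41 dense tiles, and the test treats tiles as independent. Dense tiles have lower levels and sum counts over more CpGs, and CpG number was not separated from either.

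The largest loss in K9M lay on chromosome 7 from 132021001 to 132022000, at 91.4% in WT (95% counting interval 78.7% to 106%), 10.5% ± 1.04 (SD, n = 2) in K9M and 98.2% ± 9.81 (SD, n = 2) in K36M, with an adjusted p of 0.000182 by the logistic model moderated with limma. Other losses were on chromosome 7 from 87975001 to 87976000, 78.4% to 30.8% ± 2.85 with K36M at 64.1% ± 1.12, chromosome 1 from 172880001 to 172881000, 90.5% to 44.1% ± 8.05 with K36M at 87.2% ± 2.33, chromosome 2 from 127978001 to 127979000, 60.04% to 17.6% ± 1.79 with K36M at 41.5% ± 4.64, and chromosome 12 from 57625001 to 57626000, 62.9% to 23.2% ± 3.40 with K36M at 49.1% ± 5.08 (SD, n = 2 each). The call from 87975001 was lost at a coverage minimum of 5 reads and with the plateau from the top 40% of tiles, at adjusted p of 0.0586 and 0.0610 by the logistic model moderated with limma. The largest gain was on chromosome 17 from 39148001 to 39149000, from 17.3% in WT to 82.0% ± 11.1 (SD, n = 2) in K9M, with K36M at 22.0% ± 3.08 (SD, n = 2). Gains followed on chromosome 11 from 67481001 to 67482000, 22.6% to 80.7% ± 4.24 with K36M at 57.7% ± 15.9, in the tile of chromosome 7 named above, and on chromosome 16 from 3632001 to 3633000, 43.9% to 99.6% ± 4.13 with K36M at 37.6% ± 10.6 (SD, n = 2 each). The last, on chromosome 19 from 43908001 to 43909000, went from 14.2% to 69.7% ± 9.90 with K36M at 29.0% ± 3.01 (SD, n = 2 each). With limma on relative levels, all 10 tiles named for K9M against WT lost their call, at adjusted p from 0.105 to 0.751 by limma.

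**Figure D4:**
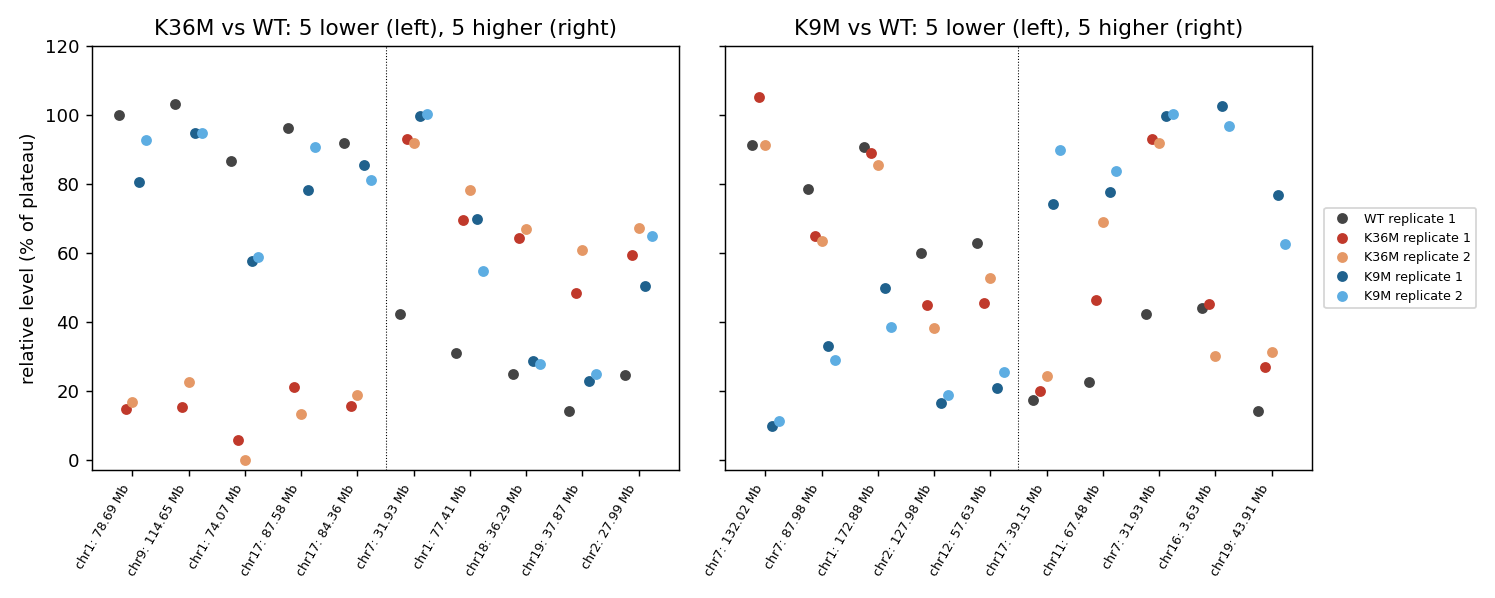
Relative level (y axis, percent of plateau) of the named tiles of K36M against WT and of K9M against WT (x axis, chromosome and start in Mb, mm9), a point per library, with losses left and gains right of the dotted line. In the 5 losses of K36M, both K36M points lie below all others.

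K36M against K9M, the comparison with 2 libraries on both sides, gave 2163 lower and 140 higher tiles, and 93.9% of calls were losses in K36M. Of the 2 K9M libraries, replicate 2 was read on another unit and aligned by its plateau. The median difference over all tiles was -1.54 points, -0.186 without K9M replicate 2 and -2.72 without K9M replicate 1. The shift over all tiles thus rested largely on K9M replicate 2. Without 1 mutant library, the lower calls numbered 2587 to 2968 and the higher calls 259 to 401, and the share of losses was 87.0% to 91.6%, in fits with 1 residual degree of freedom. limma on relative levels called 197 and 3. Losses in tiles of 20% to 80% numbered 1659, by a mean level that includes K36M, so a large loss can itself place a tile there. The largest losses lay on chromosome 12 from 17009001 to 17010000, 99.5% ± 11.2 in K9M against 12.4% ± 7.21 in K36M, and on chromosome 8 from 106946001 to 106947000, 97.6% ± 1.64 against 13.3% ± 1.55 (SD, n = 2 each), with WT at 77.4% and 74.6%. On chromosome 8 from 87245001 to 87246000, with 15 CpGs, K9M was at 86.1% ± 8.97 and K36M at 3.57% ± 0.123 (SD, n = 2 each), at an adjusted p of 6.95e-08 by the logistic model moderated with limma, and WT was at 61.5%. On chromosome 7 from 149728001 to 149729000 the levels were 95.5% ± 0.411 and 18.3% ± 3.31 (SD, n = 2 each) with WT at 67.9%, and the fifth loss was the chromosome 9 tile named above. The largest gain in K36M was the loss of K9M on chromosome 7 from 132021001. The next, on chromosome 9 from 75357001 to 75358000, had K36M at 173% ± 39.2 (SD, n = 2), above any possible level, and WT at 117%, so its value is not reliable, and its call was lost at a coverage minimum of 5 reads and without K36M replicate 1. On chromosome 7 from 70947001 to 70948000 the K9M replicates stood at 0.655% and 43.4%, against 99.3% ± 7.37 (SD, n = 2) in K36M and 48.3% in WT. Its adjusted p of 0.0477 by the logistic model moderated with limma rose to 0.0840 under edgeR, 0.0780 and 0.0536 at coverage minimums of 5 and 20 reads, 0.0510 with X and 0.0830 with the plateau from the top 40% of tiles, so the call was lost under each of these. Gains on chromosome 19 from 58463001 to 58464000 and on chromosome 17 from 69549001 to 69550000 ran from 44.5% ± 13.1 to 98.7% ± 11.8 and from 28.9% ± 9.56 to 73.5% ± 9.30 (SD, n = 2 each) with WT at 80.4% and 68.6%, the former lost at a coverage minimum of 5 reads. With limma on relative levels the 4 gains after the first lost their call, at adjusted p from 0.0802 to 0.125 by limma, while the 5 losses and the first gain kept theirs, each at 0.0434.

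Of the 924 losses in K36M against WT, 750 were also called against K9M, a comparison that shares the K36M libraries and so is no separate check. Against WT, K36M and K9M shared 23 losses and 13 gains, and 13 tiles were called in opposite directions. Without 1 mutant library the shared losses rose to 72 to 126 and the shared gains to 36 to 52, from longer lists of calls in fits with 1 residual degree of freedom. Unchanged groups simulated against the same WT library shared 0 losses and 0 gains, but that simulation made 0 and 1 calls in the 2 comparisons, so its overlap could not exceed 0 and sets no scale for 23 and 13. Independent lists of these lengths would share 0.351 and 0.0252, and 0.679 tiles would be called in opposite directions. The excess over independent lists was thus not confined to a shared direction. At an unadjusted p under 0.05 with at least 10 points, a count chosen after seeing the data, K36M and K9M shared 384 of 4126 and 939 losses and 127 of 504 and 1265 gains, where independent lists would share 25.4 and 4.18. The unchanged groups shared 188 of 739 and 747 losses and 151 of 719 and 738 gains, from lists of other lengths, so these overlaps are not values expected for the observed lists without a change. The covariance of the differences from WT across tiles was 28.5, below the 42.8 of unchanged groups simulated with the shared WT library. With 1 WT library the control could not be split, and part of the overlap may come from it.

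X carried 2.57% of the second counts in WT, 2.51% and 2.53% in K36M and 2.54% and 2.54% in K9M, over CpGs with a second count of at least 5 in all libraries. Of the deposited totals, which are not comparable under the reading used here, it carried 3.16% to 3.24% in 4 libraries and 2.64% in K9M replicate 2. The mean relative level of 4699 X tiles was 76.9% in WT, 76.1% and 77.1% in K36M and 76.5% and 78.3% in K9M.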

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

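X-chromosome tiles lie outside the main tests and were looked at because some passed the same threshold when X was added to the fit. Of 4699 X tiles, 4 were lower and 6 higher in K36M against WT, 9 were higher in K9M against WT, and 16 were lower and 1 higher in K36M against K9M. The sex of the animals is not in the labels. Across the libraries, X carried 2.51% to 2.57% of the second counts and Y carried 0.0645% to 0.0705%. Shares this alike argue against a difference in sex between the libraries. No other explanation was tested for these tiles.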

How the results depend on the processing

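Other plateaus, deposited levels without rescaling, limma on relative levels, level classes set by K9M and class or global means without a mutant library were chosen after seeing the data. Counts are given as lower and higher for K36M against WT, K9M against WT and K36M against K9M, in that order; the main counts are 924 and 35, 58 and 110, 2163 and 140. edgeR's quasi-likelihood test gave 1554 and 66, 135 and 231, 3031 and 205. limma on log2 ratios gave 1539 and 64, 105 and 194, 3410 and 263. With no dispersion floor the counts were 1815 and 84, 159 and 253, 3469 and 248. limma on relative levels gave 3 and 0, 3 and 1, 197 and 3. It called few tiles, with 8920, 4859 and 15782 at an unadjusted p under 0.05. Each CpG alone gave 0 and 0 in all 3 comparisons by the logistic model, with 4285, 1574 and 9071 CpGs at an unadjusted p under 0.05. Levels as deposited gave 0 and 0 in all 3, with 256, 175 and 1036 tiles at an unadjusted p under 0.05; there the higher level of K9M replicate 2 enters the replicate spread, with a median raw dispersion of 24.7 against 0.518. The cause of the other differences was not tested.

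With no minimum difference, higher calls rose to 56 in K36M against WT and 273 in K36M against K9M; with 20 points they were 19 and 87, and K9M had 33 lower tiles. Tiles of 500 bp gave 17 higher in K36M against WT. At least 5 CpGs per tile gave 88 lower in K9M against WT, and the plateau from the top 10% of tiles gave 103 lower and 184 higher there. Coverage minimums of 5 and 20 reads, tiles of 5 kb, the X chromosome and removal of the most deeply covered CpGs kept each count of called tiles within 1.5 times.

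The replicate block gave 1896 and 102, 294 and 378, 3665 and 341. The labels do not say that a replicate number marks a shared day or litter, and across tiles the same-numbered deviations of K36M and K9M had a Pearson correlation of 0.0773, so the numbers are not taken as pairs. Leaving out a library gave 1549 to 2033 lower and 123 to 159 higher tiles in K36M against WT, 220 to 342 and 343 to 478 in K9M against WT, and 2174 to 2968 and 141 to 401 in K36M against K9M. The block and each fit without a mutant library keep 1 residual degree of freedom, where the moderation took the prior spread as exact and used the trend alone. These larger counts therefore do not show a stronger effect.

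The global difference of K36M from WT was -1.12 points and became -0.953 with the mean of CpG levels, -1.42 and -0.614 with plateaus from the top 10% and 40% of tiles, and -0.551 with deposited levels. K9M minus WT, -0.376 points, became -0.519 at 20 reads, 0.519 with the mean of CpG levels, -0.214 and -0.710 with these plateaus, and 4.02 with deposited levels. K36M minus K9M, -0.742 points, became -1.47 with the mean of CpG levels, -1.21 and 0.0960 with these plateaus, and -4.57 with deposited levels. The K36M difference from WT in tiles of 20% to 80%, -6.58 points, became -6.71 and -6.35 with these plateaus and -5.53 with classes set by the K9M libraries, and in tiles over 80%, -1.65 points, it became -0.598 with the plateau from the top 40%. These moves exceed the SD of the 2 K36M libraries, 0.0942 and 0.840. The other class differences moved by less than their group's SD under the settings tried for them. Leaving out either library of a pair always moves the mean by less than that SD, so that setting is no check. Besides it, the classes by CpG number were run only with other coverage minimums, and other plateaus were not tried on them. The overlap against WT, 23 lower and 13 higher, was 39 lower with no minimum difference and 12 with 20 points, and 72 to 126 lower and 36 to 52 higher without a mutant library.

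Of the named tiles' results under alternatives, 434 stayed past the threshold and 35 no longer passed it. Of the latter, 24 were under limma on relative levels: all 10 of K36M against WT, all 10 of K9M against WT and 4 of 10 of K36M against K9M. The 434 include 30 with no dispersion floor, a setting that can only lower p-values and so could lose no call. They also include 29 or 30 from the replicate block and from each fit without a mutant library. In those fits the moderation took the prior spread as exact. The total of 434 is therefore no measure of how well the calls held. Thinning each CpG to 10 reads was not run, because the overlapping counts do not give reads, and the promoter window was not run without an annotation of this build. Simulated losses of 20 points, with the real totals and fitted dispersions, were recovered in 2% of tiles in K36M against WT. Only tiles at a level of 50% to 80% were lowered there, so other levels were not covered. In the data, 628 of the 924 called losses in K36M against WT were 20 points or more, so smaller differences were also called.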

Other observations

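The tests below were chosen after the values they bear on had been seen, except the test of single C-to-T variants, which was written before its result.

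K9M replicate 2, as deposited, lies far above the other libraries. Higher methylation in its cells alone would leave the deposited total independent of the level in the other 4 libraries, where a ratio of 1 is expected. The total at fully methylated CpGs was up to 2.37 times that at unmethylated ones, relative to K9M replicate 2. This bears on the unit of those 4 libraries and cannot exclude higher methylation in K9M replicate 2 as well. On relative levels K9M replicate 2 still lay 6.80 points above WT in the bin from 80%, against -1.25 points for K9M replicate 1. The plateau hides a rise that scales all CpGs alike. A level computed as methylated reads over methylated reads plus a count of less than 1 per read of either kind needs a ratio above 2, and the smallest of the 4 was 2.20, so a difference in the deposited unit is a candidate explanation. The step that would make it stays unknown, and the relative levels rest on this reading.

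The lower level of K36M in tiles of 20% to 80% is the pattern a biologist may want to follow up. A wrong library factor would lower all tiles in proportion. The ratio to WT was lower in these tiles than in tiles over 80% by at least 8.61 percentage points in both K36M libraries. The classes include K36M, so a loss that moves a tile from the higher class to the middle one widens this gap. With classes set by the K9M libraries, the K36M difference was -5.53 points at 20% to 80% and -1.97 points over 80%. A proportional factor would give the larger difference over 80%. K9M replicate 2 also departed from proportion, at 105.5% and 102.9% of WT, so an error that is not proportional is not excluded. Shallow tiles do not carry the lower K36M level alone, since in the deepest of 4 equal bins by depth the mean difference was still -5.81 points. Doxycycline alone would move K9M too, and the K9M libraries were at -0.385 and 3.35 points from WT. No library is labelled as having doxycycline without a mutant, so an effect of doxycycline cannot be told apart from that of the lysine 9 mutant. A different mix of cell types among the sorted cells was not tested, as no marker could be placed on these coordinates. A deviating WT library would leave K36M and K9M alike, but the higher K36M library minus the lower K9M library was -6.13 points in these tiles. Without WT, 2174 tiles were called lower in K36M than in K9M. The lone WT library enters that comparison only through the dispersion trend, so this count is no added check. The size of the difference from WT still rests on 1 library. A loss that follows the lysine 36 mutant remains a hypothesis.

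The 924 called losses in K36M were examined for sequence variants. A single C-to-T variant reads as 1 lost CpG, but without the most lowered CpG of each tile the median difference was still -21.6 points. Strain intervals limited to few windows would gather the losses, but 69.4% lay outside the densest 26 of 504 windows of 5 Mb, the losses touched 275 windows and 19 autosomes, and no window held more than 19, which argues against such intervals as the source of all losses. The densest 26 windows held 30.6%, against 18.5% for as many random tiles, which touched 386 windows on average. Whether strain intervals may account for part of the losses stays open, since no table separates them from other clustering.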
